A study of Mus musculus with 10 samples.

How the data were processed

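The livers were from C57Bl/6 mice, per the labels. PBC mice received 100 µg of the antigen intraperitoneally at days 0, 14 and 28, and 2 µg of α-galactosylceramide intravenously on the first 2 of these days, per the labels' protocols. PSC mice received 0.089 percent DDC for 2 weeks, normal food for 1 week and DDC for 1 week, so that this diet ended before collection at day 35. RNA of RIN above 8 (1 µg) went into stranded poly(A) libraries, sequenced as paired reads of 75 bases on a NextSeq 500. Sex, age and the time of day of collection are not given in the sources used here. The 4 Y-linked genes examined had 0 reads in all 10 libraries, and Xist had 416 to 3710.0.

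Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.4.0, and SAMtools, Picard, FastQC and DESeq2 were used. The counting tool, its use of strand and its treatment of reads on several genes are not given in the sources used here, so near-identical genes are reported as uncertain. The deposited signal is the number of reads per gene model after DESeq2 normalisation by the authors. The table holds 59408 gene models, of which 23454 carry a symbol, 366 merge several symbols and 28948 are at 0 in every library. Within each library the values were whole multiples of 1 step (tolerance 0.1), so reads were recovered by division by that step, 0.938 to 2.55 per read. The highest depth was 2.49 times the lowest. Size factors recomputed from the recovered reads differed from the deposited scale by -3.79% to 2.79%. On average 2263 models had 2 reads against 573 with 1, so both mates of a pair appear to be counted. Counting intervals take reads as independent and are therefore too narrow.

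The main test was limma with an intensity trend on log2(value + 1), with all 10 libraries in one fit. Genes with a value of at least 10 in at least 3 libraries were tested, 18390 in all and 14702 with a symbol. Adjusted p is by the method of Benjamini and Hochberg at a threshold of 0.05. edgeR and DESeq2 on the recovered reads were alternatives. The p-values measure the spread between mice, while counting intervals cover counting error only. Where every library of a group had 0 reads, the fold is a lower bound against 3 reads over the group. The groups, comparisons, filter, threshold, lists, alternatives and rule for named genes were chosen before the data were examined. The versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

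Of 41 gene lists fixed in advance, 40 had tested genes, and fry was applied to each in 3 comparisons with adjustment over 120 tests. Fry asks whether the genes of a set move on balance one way and does not compare them with other genes. Camera with a correlation estimated from the data, or preset at 0.01, was the alternative. Of 57 list calls, 5 held with an estimated correlation, as the adjusted p beside each shows. In every called list test, the list scores of the livers of the compared groups did not overlap. The lists hold 532 distinct tested genes, 14 of them in more than 1 list and 504 with a control mean of at least 10, while 39 members were left out as too low or absent. Symbols of 24 members were mapped by hand, among them immunoglobulin and T cell receptor loci that the file gives as single models. Counts adjusted over the list alone stand beside those adjusted over all genes.

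The named genes are 34 genes fixed in advance and given in every comparison. Added to these are the 8 largest called increases and decreases with a mean of at least 50 in the higher group, no overlap between groups and an established symbol. From each list described, up to 4 members with the smallest adjusted p are named, and called members against the direction of the list. Some genes that this rule names, 1 of them fixed in advance, are not reported here. The male-biased genes in PSC against control and the cholangiocyte genes called in PBC against control, except Krt19, were named after their values were seen. Simulated reads of 17936 genes held 94 to 195 changes of each size. In the 3 comparisons limma found 73.4%, 65.3% and 69.8% of 4-fold and 11.3%, 15.3% and 12.3% of 2-fold changes. At most 6 calls were false. A list given changes was called (adjusted p = 0.000504), and 0 of 60 tests of unchanged lists were, all without gene correlation.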

Results

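Bulk RNA sequencing was reported for the livers of 10 C57Bl/6 mice, all collected at day 35. There were 4 untreated control mice, 3 mice with a model of autoimmune primary biliary cholangitis (PBC) and 3 with a model of non-autoimmune primary sclerosing cholangitis (PSC). PBC followed immunisation with 2-octynoic acid coupled to albumin in Freund's adjuvant, with α-galactosylceramide, a glycolipid that activates NKT cells. PSC followed feeding with 3,5-diethoxycarbonyl-1,4-dihydrocollidine (DDC), a compound that injures bile ducts. No control received adjuvant or glycolipid. Recovered depth was 66.4, 69.4, 38.3 and 62.2 M (mega) reads in controls 1 to 4. It was 44.3, 51.1 and 49.7 M in PBC 7 to 9, and 95.4, 55.3 and 58.3 M in PSC 11, 13 and 14. Levels are normalised reads given as mean ± SD (n = 4, 3 and 3). Changes are log2 fold changes of the normalised reads plus 1, with adjusted p from limma, and positions are on mm10. Where leaving out 1 library or another alternative ended a call, or 1 library or tool moved the value of a called gene more than 1.5 times, the value is given with it.

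Every library lay nearest to others of its group on the first pair of principal components of the 1000 most variable genes. PC1 held 31.8% of the variance and separated all 6 cholangitis livers from the 4 controls. PC2 held 20.9% and separated PBC from PSC. Control 2 had 13.7% of its reads on mitochondrial models, against at most 8.67% elsewhere. PBC 7 had 4.24% on a gene model of ribosomal RNA repeats, against at most 0.831% elsewhere.

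**Figure D1:**
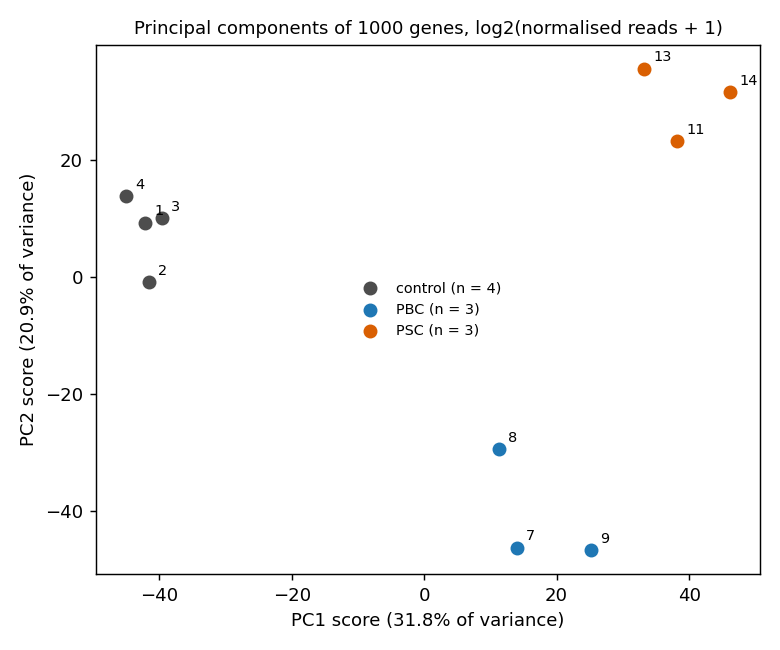
Scores of the 10 libraries on PC1 and PC2 (arbitrary units), from the 1000 most variable genes on the log2 scale. Each point is 1 liver, coloured by group and numbered by replicate, and the 3 groups occupy separate regions.

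The first comparison asked how the livers of the autoimmune model differed from untreated livers. Genes of neutrophils and their precursors gave the largest changes: 12 of 13 neutrophil genes rose, with a median log2 fold change of 5.15 and a median SE of 0.74 (n = 3 and 4). The T cell, antibody, antigen presentation, macrophage, acute phase and matrix lists rose too, of which only that of antigen presentation held with an estimated correlation, and Cd8a went from 34.7 ± 16.7 to 723 ± 144. The cholangiocyte list did not pass the test. Limma called 1398 genes higher and 430 lower among 18390 tested, with 1087 and 254 beyond 2-fold. Leaving out 1 library changed the number of higher genes to 843 without PBC 7 and 684 without PBC 9. The number of lower genes became 174 without control 1, 210 without control 3, 268 without control 4, 203 without PBC 7, 1574 without PBC 8, 65 without PBC 9, 282 without PSC 11, 237 without PSC 13 and 228 without PSC 14.

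The 8 genes with the largest increases in PBC all encode products of neutrophils or their precursors. Ltf, which encodes the granule protein lactoferrin (GSMG0040156, chromosome 9, 111019290 to 111042766), rose by 9.82 (SE 0.74, adjusted p = 2.07e-05), from 1.29 ± 2.59 to 1938 ± 1881. Mpo rose by 9.26 (SE 0.70, adjusted p = 2.07e-05), from 1.39 ± 2.77 to 1214 ± 1014, and encodes myeloperoxidase of the primary granules (GSMG0005730, chromosome 11, 87793784 to 87804411). Of antimicrobial granule genes, Camp rose by 9.36 (SE 0.74, adjusted p = 2.07e-05) and Ngp by 7.69 (SE 0.74, adjusted p = 7.78e-05). Among the granule proteases, Prtn3 rose by 7.59 (SE 0.60, adjusted p = 2.07e-05) and Elane by 7.14 (SE 0.71, adjusted p = 8.65e-05). Ctsg, another, had 3 reads in the controls together and a PBC to control ratio of 236 (95% counting interval 80.1 to 1148), with adjusted p = 0.000603. Ms4a3, a gene of granulocyte and monocyte progenitors, rose by 6.67 (SE 0.90, adjusted p = 0.000603). Of 13 neutrophil genes, 12 rose (13 over the list alone), and the list rose (adjusted p = 0.00016, or 0.0606 with an estimated correlation). S100a8, an alarmin subunit of neutrophils and monocytes, rose by 4.60 (SE 0.76, adjusted p = 0.00224). Ltf moved to 10.47 without control 1 and 9.05 without PBC 9, Camp to 8.67 without control 3 and 8.60 without PBC 9, Mpo to 9.94 without control 4 and 8.62 without PBC 9, Ngp to 8.52 without PBC 7, 6.94 without PBC 9 and 8.35 with DESeq2, Ctsg from 7.25 to 7.91 with DESeq2, Elane to 6.48 without control 3 and 6.48 without PBC 9 and S100a8 to 3.67 without control 4.

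The 8 largest decreases in PBC were smaller. Corin fell by 2.38 (SE 0.49, adjusted p = 0.00862), which encodes a protease that activates natriuretic peptide. Cd207 fell by 2.32 (SE 0.39, adjusted p = 0.00249), from 699 ± 256 to 148 ± 75.5, and encodes langerin of dendritic cells. The glutamate receptor gene Grid1 fell by 2.12 (SE 0.38, adjusted p = 0.00412). Of a potassium channel gene and a nucleoporin-like gene, Kcnk10 fell by 2.31 (SE 0.64, adjusted p = 0.0369) and Nup62cl by 2.05 (SE 0.46, adjusted p = 0.0138). Hao2, for a peroxisomal oxidase, and Tfrc, for the transferrin receptor, fell by 2.02 (SE 0.49, adjusted p = 0.0219) and 2.02 (SE 0.50, adjusted p = 0.0232). The zinc finger gene Zfp141 fell by 1.84 (SE 0.51, adjusted p = 0.0389). Kcnk10 lost its call without any 1 control, PBC 7, PBC 8 or PSC 14 (adjusted p from 0.0513 to 0.108) or with no filter (0.0619), edgeR (0.077) or only the compared groups (0.0677), Nup62cl without PBC 7 (0.0515), Hao2 without PBC 7 (0.0979) or PBC 9 (0.0888), Tfrc without control 4 (0.0525) or PBC 9 (0.0694) or with only the compared groups (0.0636) and Zfp141 without any 1 control, PBC 7, PBC 9, PSC 11, PSC 13 or PSC 14 (0.0506 to 0.138) or with no filter (0.0767), equal totals (0.0521), edgeR (0.0673) or only the compared groups (0.092). Corin moved to -3.09 without PBC 9, Kcnk10 to -1.62 without PBC 8 and -3.13 without PBC 9, Hao2 to -2.63 without PBC 8, Tfrc to -1.26 without PBC 9 and Zfp141 to -1.13 without PBC 9.

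Lymphoid lists rose in PBC. Of 19 T cell genes, 12 rose (15 over the list alone), and the list rose (adjusted p = 0.00016, or 0.0606 with an estimated correlation). Cd8a rose by 4.44 (SE 0.40, adjusted p = 5.15e-05) and Cd8b1 by 3.25 (SE 0.40, adjusted p = 0.00036), both chains of the CD8 co-receptor (Cd8a is GSMG0032048, chromosome 6, 71373427 to 71379173). Tra/Trd locus rose by 2.13 (SE 0.24, adjusted p = 0.000199) and Lat by 2.23 (SE 0.32, adjusted p = 0.000907). Cd3e, part of the T cell receptor complex, rose by 2.39 (SE 0.64, adjusted p = 0.034). Of 13 NK cell and cytotoxicity genes, 8 rose (10 over the list alone), and the list rose (adjusted p = 0.000613, or 0.132 with an estimated correlation). The NK cell count became 5 without control 1 and 4 without PBC 7. Ccl5 rose by 2.81 (SE 0.23, adjusted p = 2.07e-05) and Nkg7 by 2.20 (SE 0.22, adjusted p = 8.65e-05), and the granzyme genes Gzmb rose by 2.80 and Gzma by 1.37. Of 11 immune checkpoint and regulatory T cell genes, 2 rose (4 over the list alone), and the list rose (adjusted p = 0.00016, or 0.0868 with an estimated correlation). The checkpoint call was lost with the stricter filter (adjusted p = 0.319). The checkpoint count became 1 without PBC 7 or PBC 9. Tigit rose by 3.36 (SE 0.76, adjusted p = 0.0147), which encodes an inhibitory receptor. Of 8 lymphoid aggregate genes, 4 rose (8 over the list alone), and the list rose (adjusted p = 0.000618, or 0.0706 with an estimated correlation). Ltb and Ccl19, for a lymphotoxin and a T cell zone chemokine, rose by 1.72 (SE 0.26, adjusted p = 0.00122) and 1.72 (SE 0.29, adjusted p = 0.00259). Of 10 B cell genes, 2 rose (4 over the list alone), and the list rose (adjusted p = 0.0182, or 0.321 with an estimated correlation). The B cell call was lost without control 1, control 2, PBC 8 or PBC 9 (adjusted p from 0.05 to 0.0718), and with equal totals (0.0588). The B cell count became 1 without PBC 9. Cd22, for a B cell inhibitory receptor, rose by 2.11 (SE 0.31, adjusted p = 0.00096). Of 5 plasma cell and immunoglobulin genes, 5 rose (the same over the list alone), and the list rose (adjusted p = 0.00449, or 0.158 with an estimated correlation). Igl locus rose by 2.12, Igk locus by 2.48 and Igh locus by 2.26, and the joining chain gene Jchain rose by 2.37 (SE 0.44, adjusted p = 0.00467). Cd3e lost its call without control 1, control 4, PBC 7 or PBC 9 (adjusted p from 0.0554 to 0.103) or with no filter (0.0597) or equal totals (0.058).

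Myeloid lists rose as well. Of 16 monocyte and recruited macrophage genes, 13 rose (the same over the list alone), and the list rose (adjusted p = 0.00016, or 0.0573 with an estimated correlation). Gpnmb, a lysosomal glycoprotein gene of lipid-laden macrophages, rose by 6.34 (SE 0.60, adjusted p = 7.3e-05), and S100a4 rose by 2.32, Chil3 by 5.05 and Ly6c2 by 3.49. Trem2, for a lipid-sensing macrophage receptor, rose by 1.72 (SE 0.29, adjusted p = 0.00293). Of 12 Kupffer cell genes, 10 rose (the same over the list alone), and the list rose (adjusted p = 0.00192, or 0.158 with an estimated correlation). Among Kupffer cell genes, 9 rose and 1 fell without PBC 8. Marco, a scavenger receptor gene, rose by 4.60 (SE 0.47, adjusted p = 0.000101), from 938 ± 562 to 22743 ± 14173, and C1qa rose by 1.63, C1qb by 1.64 and C1qc by 1.68. Clec4f, for a Kupffer cell lectin, rose by 0.90 (SE 0.21, adjusted p = 0.0182). The dendritic cell list rose (adjusted p = 0.00763, or 0.298 with an estimated correlation). The dendritic cell call was lost without PBC 8 (adjusted p = 0.0878). Batf3 rose by 1.83 (SE 0.31, adjusted p = 0.00278), which encodes a transcription factor of cross-presenting dendritic cells, while Cd209a fell by 3.00 (SE 0.78, adjusted p = 0.0295). Clec4f lost its call without PBC 9 (adjusted p = 0.0925) or with only the compared groups (0.0575) and Cd209a without control 1, control 3, control 4, PBC 7, PBC 9, PSC 13 or PSC 14 (0.0502 to 0.114) or with edgeR (0.0947) or only the compared groups (0.0955). Gpnmb moved to 5.75 without control 3 and Cd209a to -3.96 without PBC 8.

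Of 16 MHC and antigen presentation genes, 14 rose (16 over the list alone), and the list rose (adjusted p = 8.09e-05, or 0.0493 with an estimated correlation). The class II genes Cd74 rose by 2.58 (SE 0.21, adjusted p = 2.27e-05), H2-Eb1 by 2.49 (SE 0.24, adjusted p = 7.78e-05) and H2-Aa by 2.23 (SE 0.24, adjusted p = 0.00015), although reads can be shared between H2 genes. Of 14 interferon gamma response genes, 8 rose (12 over the list alone), and the list rose (adjusted p = 0.00746, or 0.182 with an estimated correlation). Cxcl9 rose by 2.29 (SE 0.30, adjusted p = 0.000525). Of 19 inflammatory cytokine and chemokine genes, 14 rose (16 over the list alone), and the list rose (adjusted p = 0.000303, or 0.061 with an estimated correlation). The neutrophil chemokine gene Cxcl1 rose by 4.17 (SE 0.44, adjusted p = 0.000117), the monocyte chemokine gene Ccl2 rose by 2.82 (SE 0.32, adjusted p = 0.000212), and Vcam1 rose by 1.98 and Nfkb2 by 1.86. Of 19 acute phase genes, 16 rose (19 over the list alone), and the list rose (adjusted p = 0.000235, or 0.061 with an estimated correlation). Lcn2 rose by 6.13 (SE 0.52, adjusted p = 3.16e-05) and Orm2 by 5.18 (SE 0.40, adjusted p = 2.07e-05), with Lcn2 going from 626 ± 499.8 to 38809.5 ± 17332. The serum amyloid genes Saa1 rose by 4.28 (SE 0.48, adjusted p = 0.000198) and Saa2 by 4.79 (SE 0.51, adjusted p = 0.000131), which are similar enough to share reads.

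Of 24 extracellular matrix and stellate cell genes, 9 rose (14 over the list alone), and the list rose (adjusted p = 0.00212, or 0.158 with an estimated correlation). Among matrix genes, 10 rose and 2 fell without PBC 8. Timp1, an inhibitor of matrix proteases, rose by 4.28 (SE 0.40, adjusted p = 7.01e-05), and the collagen genes Col1a1 rose by 2.80 (SE 0.42, adjusted p = 0.00112) and Col1a2 by 1.92 (SE 0.25, adjusted p = 0.0005). Col4a1 rose by 1.54 and Col5a2 by 1.67. The cholangiocyte list did not pass (adjusted p = 0.119), although 5 of its 20 genes rose and 0 fell (6 and 1 over the list alone), or 2 to 4 and 0 to 1 with 1 library left out. The keratin gene Krt19 rose by 1.13 (SE 0.33, adjusted p = 0.046), and Sox9 rose by 1.41, Elf3 by 1.90 and Muc1 by 1.12 (adjusted p from 0.00531 to 0.0381). Of 12 p53 target and senescence genes, 3 rose (4 over the list alone), and the list rose (adjusted p = 0.00449, or 0.192 with an estimated correlation). Cdkn2a rose by 3.94 (SE 0.48, adjusted p = 0.000308) and Gdf15 by 3.52 (SE 0.58, adjusted p = 0.00228), a cell cycle inhibitor and a stress cytokine. Proliferation genes as a list did not pass (adjusted p = 0.0895), although Mki67 rose by 2.44 (SE 0.44, adjusted p = 0.00419). Krt19 lost its call without any 1 control, PBC 7, PBC 8, PBC 9, PSC 11, PSC 13 or PSC 14 (adjusted p from 0.0506 to 0.138) or with no filter (0.0604), TMM scaling (0.0522), equal totals (0.103), edgeR (0.0512), only the compared groups (0.097) or quality weights (0.0583) and Muc1 without control 1, control 3, PBC 7, PBC 9, PSC 11, PSC 13 or PSC 14 (0.0523 to 0.103) or with no filter (0.0797), equal totals (0.0976), edgeR (0.0573) or only the compared groups (0.108).

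Among hepatocyte lists in PBC, that of xenobiotic cytochromes P450 rose (adjusted p = 0.031, or 0.363 with an estimated correlation). The P450 call was lost without PBC 7, PBC 8, PBC 9, PSC 11, PSC 13 or PSC 14 (adjusted p from 0.0527 to 0.0975), and with equal totals (0.167) or only the compared groups (0.121). Cyp2b10, the classical target of the receptor CAR, rose by 4.08 (SE 0.43, adjusted p = 0.000123), from 764 ± 402 to 11661 ± 2422 (GSMG0034189, chromosome 7, 25897658 to 25926624). Cyp2c29 rose by 1.37 (SE 0.22, adjusted p = 0.00219) and Cyp2c50 by 1.18 (SE 0.19, adjusted p = 0.0021). The periportal hepatocyte list rose (adjusted p = 0.0463, or 0.418 with an estimated correlation). The periportal call was lost without control 1, control 2, control 3, PBC 7, PBC 9, PSC 11, PSC 13 or PSC 14 (adjusted p from 0.0566 to 0.127), and with equal totals (0.232) or only the compared groups (0.115). The unfolded protein response list rose (adjusted p = 0.0441, or 0.351 with an estimated correlation). The unfolded protein response call was lost without control 1, control 4, PBC 7, PBC 9, PSC 11, PSC 13 or PSC 14 (adjusted p from 0.0549 to 0.128), and with TMM scaling (0.057) or only the compared groups (0.0725). The immediate early list rose (adjusted p = 0.0441, or 0.298 with an estimated correlation). The immediate early call was lost without control 1, control 4, PBC 8, PBC 9, PSC 11, PSC 13 or PSC 14 (adjusted p from 0.0582 to 0.151), and with TMM scaling (0.0574), equal totals (0.0984), only the compared groups (0.0725) or quality weights (0.0772). Ier3 rose by 1.37 (SE 0.27, adjusted p = 0.00595). Hmox1, for heme oxygenase, rose by 1.63 (SE 0.29, adjusted p = 0.00362).

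The other lists did not pass in PBC. Of immunity, stress, sex bias and lipid metabolism, these were type I interferon response, NRF2 target, female-biased liver gene, male-biased liver gene, cholesterol synthesis, fatty acid synthesis and PPAR alpha target and fatty acid oxidation (adjusted p from 0.118 to 0.882). Of bile acids, heme and other cell types, they were bile acid synthesis, hepatocyte bile acid uptake and canalicular export, basolateral bile acid export and FXR target, heme synthesis and degradation, hepatocyte secreted protein, pericentral hepatocyte, circadian clock, sinusoidal endothelial cell, erythroid, pancreatic acinar and mesothelial (adjusted p from 0.0584 to 0.843). The test, the median and the mean differed in sign for bile acid synthesis (up, 0.06 and -0.00) and erythroid genes (up, -0.00 and 0.29). Among genes fixed in advance, the log2 fold change did not pass for the biliary and stellate cell genes, at 0.49 for Krt7, -0.67 for Epcam and 1.01 for Acta2 (adjusted p from 0.0964 to 0.401). Lymphocyte genes gave 0.95 for Cd4, 1.07 for Cd274, 2.74 for Pdcd1, 2.67 for Foxp3 and -0.21 for Ms4a1 (adjusted p from 0.0554 to 0.838). Bile acid genes gave -1.20 for Cyp7a1, 0.57 for Cyp8b1, 0.27 for Abcb11, -0.15 for Slc10a1 and -0.01 for Abcc4 (adjusted p from 0.277 to 0.992). Other hepatocyte and stress genes gave -0.42 for Alas1, -0.66 for Fech, -0.30 for Nqo1, 0.33 for Alb and 1.55 for Cdkn1a (adjusted p from 0.0849 to 0.613). Fech passed without PBC 8 (adjusted p = 0.0135).

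**Figure D2:**
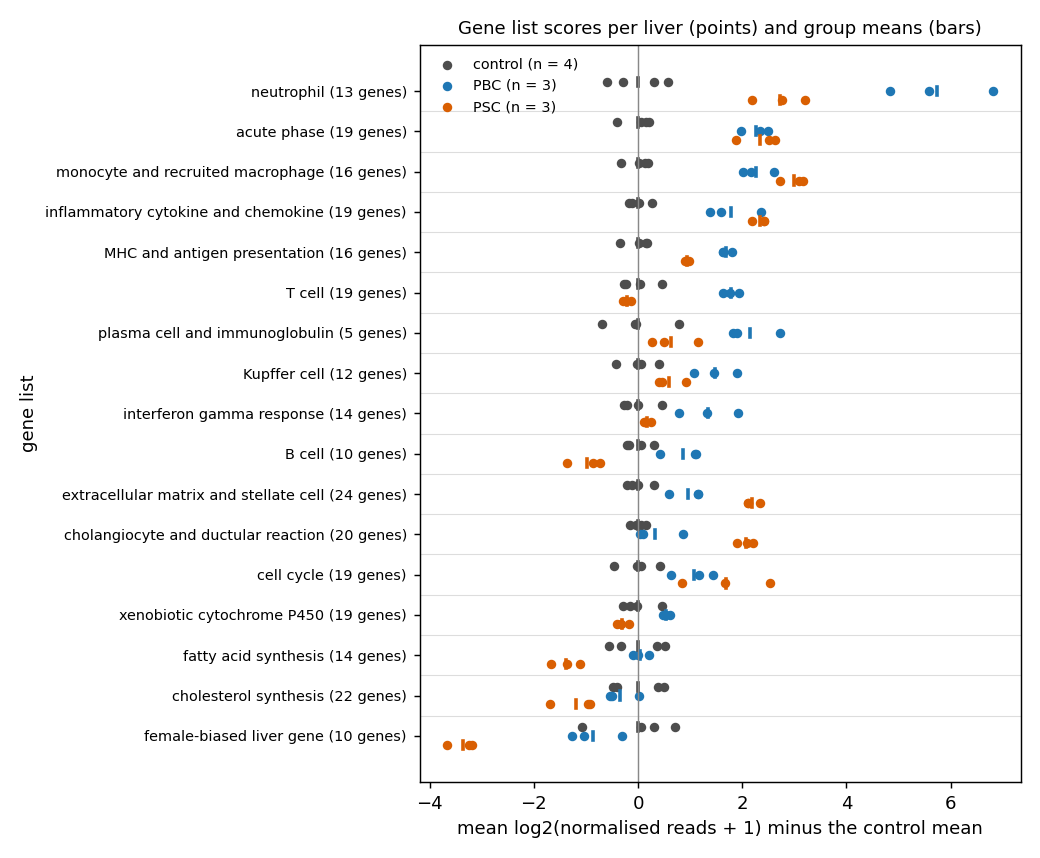
Scores of 17 gene lists in each liver, as the mean log2 normalised reads over the list minus the control mean. Points are livers, bars are group means, and colours mark control (n = 4), PBC (n = 3) and PSC (n = 3). Neutrophil and T cell scores stand highest in PBC, while cholangiocyte and matrix scores stand highest in PSC.

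The next comparison asked how the livers of the DDC model differed from untreated livers. Biliary and matrix genes gave a broad increase in PSC: 13 of 20 cholangiocyte genes and 19 of 24 matrix and stellate cell genes rose, with median log2 fold changes of 2.12 (median SE 0.39) and 1.90 (median SE 0.27, n = 3 and 4). All 16 genes tested of monocytes and recruited macrophages rose, and Col1a1 went from 149 ± 88.4 to 5129 ± 809.6. The lists of lipid synthesis fell but did not hold with an estimated correlation, and all 10 female-biased liver genes tested fell, while the T cell list did not pass. Limma called 1518 genes higher and 1192 lower among 18390 tested, with 1242 and 891 beyond 2-fold. Leaving out 1 library changed the number of higher genes to 838 without PSC 11, 925 without PSC 13 and 711 without PSC 14. The number of lower genes became 521 without control 1, 794 without control 2, 759 without control 4, 1899 without PBC 8, 493 without PSC 11, 509 without PSC 13 and 251 without PSC 14.

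Among the 8 largest increases in PSC was Sprr1a, an epithelial cornified envelope gene (GSMG0025679, chromosome 3, 92483955 to 92485895). It had 2 reads in the controls together against 2067 ± 944 normalised reads in PSC, a ratio of 2774 (95% counting interval 768 to 22920.0), with adjusted p = 1.76e-06. The macrophage genes Gpnmb rose by 9.59 (SE 0.60, adjusted p = 1.2e-06) and Mmp12 by 7.17 (SE 0.39, adjusted p = 1.17e-06), the latter encoding macrophage elastase (Gpnmb is GSMG0031858, chromosome 6, 49036518 to 49070929). Lcn2, for an iron-scavenging acute phase protein, rose by 7.05 (SE 0.52, adjusted p = 3.77e-06). Ubd, for a ubiquitin-like protein induced by cytokines, and Ly6d, for a surface protein, rose by 6.66 (SE 0.38, adjusted p = 1.17e-06) and 6.59 (SE 0.48, adjusted p = 3.6e-06). The trypsin inhibitor gene Spink1 rose by 6.45 (SE 0.54, adjusted p = 9.71e-06), and Saa2 rose by 6.25 (SE 0.51, adjusted p = 8.09e-06). Sprr1a moved from 10.43 to 11.07 with edgeR and 11.38 with DESeq2, Gpnmb to 9.00 without control 3 and Saa2 to 6.88 without PSC 13.

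Genes of sulfotransferases, cytochromes P450 and a major urinary protein were among the 8 largest decreases. Sult3a1 fell by 6.79 (SE 0.44, adjusted p = 1.26e-06), from 17472 ± 6628 to 153 ± 46.9 (GSMG0002859, chromosome 10, 33857722 to 33879475), and its near-identical neighbour Sult3a2 fell by 6.87 (SE 0.82, adjusted p = 0.000201), so their split is uncertain. Mup19 fell by 6.98 (SE 1.59, adjusted p = 0.0118), and reads can be shared among major urinary protein genes. The related P450 genes Cyp3a44 fell by 5.08 (SE 0.65, adjusted p = 0.000346) and Cyp3a16 by 5.03 (SE 1.13, adjusted p = 0.0111), likewise with shared sequence. The pseudogene Serpina4-ps1 fell by 6.09 (SE 1.34, adjusted p = 0.00987), the homeobox gene Cdx4 fell by 6.06 (SE 0.85, adjusted p = 0.000641), and Msmp fell by 5.77 (SE 0.50, adjusted p = 1.23e-05). Mup19 moved to -7.85 without PSC 11, -4.15 without PSC 13, -8.94 without PSC 14, -4.54 with edgeR and -4.51 with DESeq2, Sult3a2 to -7.64 without PSC 11, -5.64 without PSC 14 and -6.25 with edgeR, Serpina4-ps1 to -5.08 without control 2, -7.50 without control 4, -7.77 with edgeR and -7.75 with DESeq2, Cdx4 to -7.19 without PSC 11, Cyp3a44 to -5.75 without control 3 and Cyp3a16 to -4.39 without control 2, -6.49 without control 3, -4.32 without control 4, -6.33 with edgeR and -6.33 with DESeq2.

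Of 20 cholangiocyte and ductular reaction genes, 13 rose (14 over the list alone), and the list rose (adjusted p = 0.000117, or 0.0456 with an estimated correlation). Spp1 rose by 3.04 (SE 0.25, adjusted p = 8.98e-06) and Tspan8 by 3.40 (SE 0.30, adjusted p = 1.5e-05), osteopontin and a tetraspanin of bile duct cells, and Elf3 rose by 3.74 and Cldn4 by 3.77. The biliary keratin and adhesion genes Krt19 rose by 2.11 (SE 0.33, adjusted p = 0.00139), Krt7 by 2.00 (SE 0.35, adjusted p = 0.00279) and Epcam by 1.50 (SE 0.35, adjusted p = 0.0143). Of 24 extracellular matrix and stellate cell genes, 19 rose (21 over the list alone), and the list rose (adjusted p = 8.09e-05, or 0.0606 with an estimated correlation). Among collagens, Col1a1 rose by 5.24, Col1a2 by 3.91, Col3a1 by 3.93 and Col4a1 by 2.69 (adjusted p from 1.26e-06 to 6.56e-06, and Col1a1 is GSMG0005795, chromosome 11, 94936224 to 94953040). Timp1 rose by 6.14 (SE 0.40, adjusted p = 1.26e-06) and Acta2 by 2.26 (SE 0.37, adjusted p = 0.00173), the latter encoding smooth muscle actin of activated stellate cells. Of 19 cell cycle genes, 13 rose (16 over the list alone), and the list rose (adjusted p = 0.0175, or 0.292 with an estimated correlation). The cell cycle call was lost without PSC 14 (adjusted p = 0.0536). The cell cycle count became 8 without control 1 or PSC 14 and 7 without PSC 11. Cdk1 rose by 1.86 (SE 0.34, adjusted p = 0.00333) and Mki67 by 2.43 (SE 0.44, adjusted p = 0.00354). Of 12 p53 target and senescence genes, 5 rose (10 rose and 1 fell over the list alone), and the list rose (adjusted p = 0.000475, or 0.0811 with an estimated correlation). Among p53 target genes, 5 rose and 1 fell without control 4 or PBC 9, 6 rose and 1 fell without PBC 8 and 3 rose and 0 fell without PSC 14. Phlda3 rose by 3.19 (SE 0.25, adjusted p = 5.59e-06) and Gdf15 by 3.20 (SE 0.58, adjusted p = 0.00349). Epcam lost its call without PSC 13 (adjusted p = 0.0619) or PSC 14 (0.0857).

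**Figure D3:**
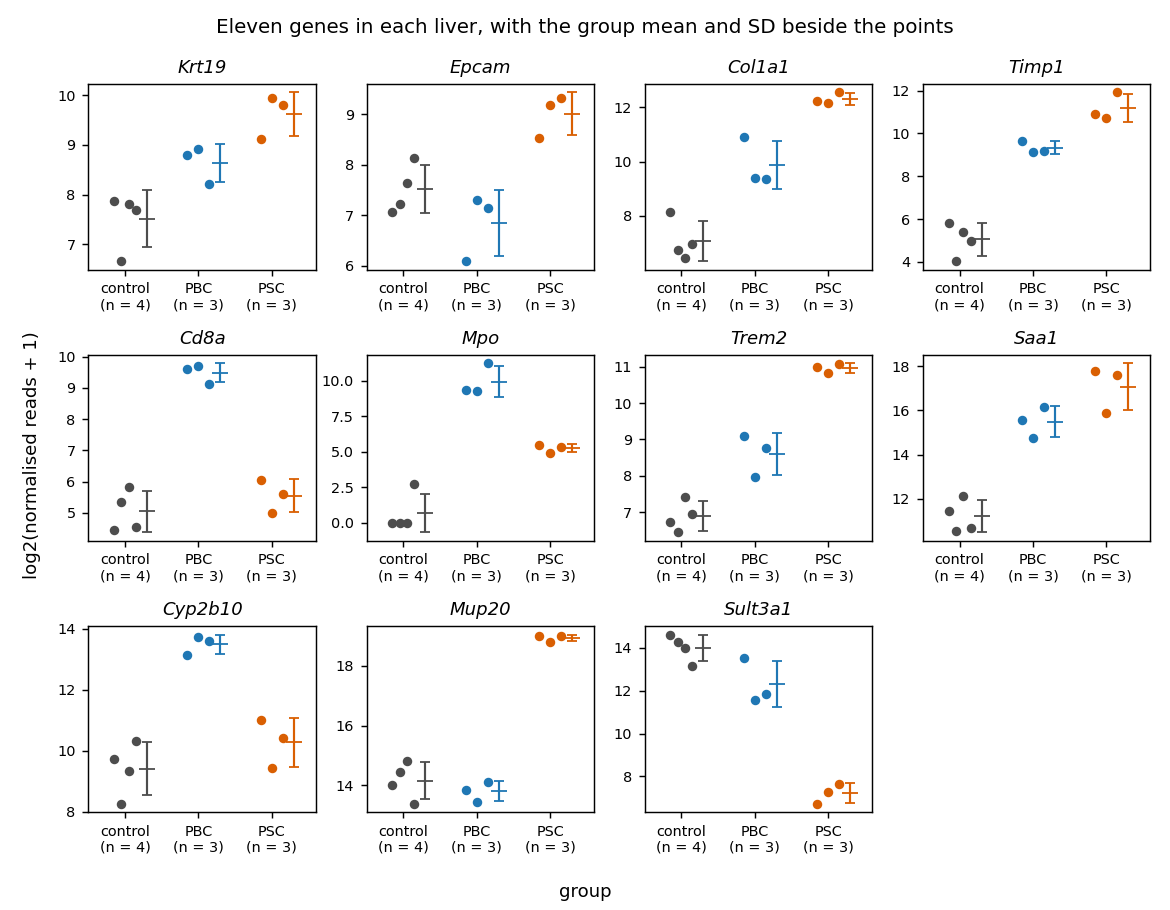
Levels of 11 genes in each liver, as log2 of normalised reads plus 1, by group. Points are livers, and the mark beside them is the group mean with its SD (n = 4, 3 and 3). Cd8a and Cyp2b10 stand highest in PBC, whereas Col1a1 and Mup20 stand highest in PSC.

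Of 16 monocyte and recruited macrophage genes, 16 rose (the same over the list alone), and the list rose (adjusted p = 8.09e-05, or 0.0456 with an estimated correlation). Trem2 rose by 4.07 (SE 0.29, adjusted p = 3.6e-06) and S100a4 by 2.78 (SE 0.25, adjusted p = 2.06e-05). Of 13 neutrophil genes, 8 rose (11 over the list alone), and the list rose (adjusted p = 0.00654, or 0.158 with an estimated correlation). The neutrophil count became 5 without control 1, control 2 or PSC 13, 4 without PSC 11 and 3 without PSC 14. Camp rose by 5.54 (SE 0.74, adjusted p = 0.000435), Ltf by 5.16 (SE 0.74, adjusted p = 0.000815) and Mpo by 4.57 (SE 0.70, adjusted p = 0.00126), and S100a8 rose by 2.52 (SE 0.76, adjusted p = 0.0404). The Kupffer cell list rose (adjusted p = 0.0456, or 0.507 with an estimated correlation). The Kupffer cell call was lost without control 1, control 2, control 3, PBC 7, PBC 8, PBC 9, PSC 11, PSC 13 or PSC 14 (adjusted p from 0.0558 to 0.147), and with equal totals (0.131) or only the compared groups (0.0996). The complement genes C1qa rose by 1.25, C1qb by 1.45 and C1qc by 1.11. The dendritic cell list rose (adjusted p = 0.00763, or 0.237 with an estimated correlation). Batf3 rose by 1.41 (SE 0.31, adjusted p = 0.0102). Of 16 MHC and antigen presentation genes, 8 rose (9 over the list alone), and the list rose (adjusted p = 0.000482, or 0.105 with an estimated correlation). H2-Eb1 rose by 2.15 (SE 0.24, adjusted p = 0.000109) and Cd74 by 1.68 (SE 0.21, adjusted p = 0.000316). Of 19 inflammatory cytokine and chemokine genes, 15 rose (18 over the list alone), and the list rose (adjusted p = 0.00016, or 0.0606 with an estimated correlation). Ccl2 rose by 3.97 (SE 0.32, adjusted p = 7.72e-06) and Vcam1 by 1.73 (SE 0.19, adjusted p = 0.000107). Of 19 acute phase genes, 14 rose (the same over the list alone), and the list rose (adjusted p = 0.000252, or 0.0766 with an estimated correlation). Saa1 rose by 5.88 (SE 0.48, adjusted p = 8.12e-06) and Orm2 by 4.86 (SE 0.40, adjusted p = 8.29e-06). S100a8 lost its call without control 1, control 2, PSC 11, PSC 13 or PSC 14 (adjusted p from 0.0509 to 0.134) or with edgeR (0.0594) or DESeq2 (0.0716). Camp moved to 4.86 without control 3, Ltf to 5.81 without control 1, Mpo to 5.25 without control 4, S100a8 to 1.60 without control 4, 1.92 with edgeR and 1.94 with DESeq2 and Saa1 to 6.48 without PSC 13.

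Lymphoid lists did not move together in PSC. The T cell list did not pass (adjusted p = 0.506), and neither did those of the lymphoid aggregate (adjusted p = 0.116), plasma cell and immunoglobulin (adjusted p = 0.35) and immune checkpoint and regulatory T cell (adjusted p = 0.702). The NK cell and cytotoxicity list rose (adjusted p = 0.0279, or 0.363 with an estimated correlation). The NK cell call was lost without control 1, control 2, PBC 7, PSC 11, PSC 13 or PSC 14 (adjusted p from 0.0509 to 0.0853), and with equal totals (0.0588) or only the compared groups (0.0573). Ccl5 rose by 1.27 (SE 0.23, adjusted p = 0.00296). Of 10 B cell genes, 4 fell (6 over the list alone), and the list fell (adjusted p = 0.0186, or 0.292 with an estimated correlation). The B cell call was lost without PSC 11 (adjusted p = 0.0562). The B cell count became 1 without control 1, 2 without control 3, control 4, PSC 13 or PSC 14 and 0 without PSC 11. Ms4a1 fell by 1.99 (SE 0.52, adjusted p = 0.0226), a B cell surface marker. The interferon gamma list did not pass (adjusted p = 0.772), although the chemokine gene Cxcl9 rose by 1.44 (SE 0.30, adjusted p = 0.00762). Its median was -0.04 and its mean 0.17, while its test pointed up. Ms4a1 lost its call without control 1, control 4, PSC 11, PSC 13 or PSC 14 (adjusted p from 0.051 to 0.0853) and Cxcl9 without PSC 14 (0.0544).

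Hepatocyte lists of bile acid transport and lipid synthesis fell in PSC. Of 11 bile acid uptake and canalicular export genes, 1 rose and 5 fell (1 rose and 9 fell over the list alone), and the list fell (adjusted p = 0.000303, or 0.0606 with an estimated correlation). Among bile acid transport genes, 0 rose and 3 fell without control 1 or PSC 13, 0 rose and 6 fell without control 3, 0 rose and 4 fell without control 4, 0 rose and 1 fell without PSC 11 and 0 rose and 0 fell without PSC 14. The uptake carrier genes Slco2b1 fell by 0.79 (SE 0.18, adjusted p = 0.0139) and Slco1b2 by 0.87 (SE 0.22, adjusted p = 0.0192), while Abcb4, the phospholipid exporter of bile, rose by 0.76 (SE 0.22, adjusted p = 0.0341). The basolateral bile acid export and FXR target list rose (adjusted p = 0.0255, or 0.378 with an estimated correlation). The FXR target call was lost without PBC 8 (adjusted p = 0.0878), PBC 9 (0.0678) or PSC 14 (0.0715), and with equal totals (0.0637), only the compared groups (0.186) or camera at the preset correlation (0.198). Abcc3 rose by 1.08 (SE 0.17, adjusted p = 0.00118), a basolateral conjugate exporter. Of 22 cholesterol synthesis genes, 12 fell (17 over the list alone), and the list fell (adjusted p = 0.0186, or 0.224 with an estimated correlation). The cholesterol synthesis call was lost without PSC 13 (adjusted p = 0.0646). The cholesterol synthesis count became 7 without control 1 and 4 without PSC 13. Sc5d fell by 1.75 (SE 0.26, adjusted p = 0.000919) and Hsd17b7 by 2.51 (SE 0.38, adjusted p = 0.00118). Of 14 fatty acid synthesis genes, 9 fell (the same over the list alone), and the list fell (adjusted p = 0.00654, or 0.105 with an estimated correlation). The fatty acid synthesis count became 5 without PSC 13 and 4 without PSC 14. Gpam fell by 2.42 (SE 0.39, adjusted p = 0.00166) and Pnpla3 by 3.30 (SE 0.56, adjusted p = 0.00217). Slco2b1 lost its call without PSC 14 (adjusted p = 0.0769), Slco1b2 without control 1 (0.0531), PSC 11 (0.0866) or PSC 14 (0.0747) and Abcb4 without control 1, control 3, control 4, PSC 11, PSC 13 or PSC 14 (0.0575 to 0.134) or with no filter (0.0542).

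Of 10 female-biased liver genes, 10 fell (the same over the list alone), and the list fell (adjusted p = 0.000475, or 0.061 with an estimated correlation). Besides Sult3a1, Cyp17a1 fell by 2.41 (SE 0.37, adjusted p = 0.00135). The male-biased list did not pass (adjusted p = 0.629), and of its 7 genes 1 rose and 3 fell (the same over the list alone), or 1 fell without PSC 11 or PSC 13. Elovl3 fell by 2.58 (SE 0.39, adjusted p = 0.00107), Hsd3b5 by 4.20 (SE 1.03, adjusted p = 0.0172) and Slco1a1 by 4.45 (SE 1.12, adjusted p = 0.0193). Mup20 rose by 4.76 (SE 0.29, adjusted p = 1.2e-06), from 19556 ± 7696 to 499337 ± 36812 (GSMG0027882, chromosome 4, 62050237 to 62054143), and encodes a pheromone of a family with shared reads. The male-biased test pointed up, while its median was -0.25 and its mean -0.72. Of 15 unfolded protein response genes, 5 rose (7 over the list alone), and the list rose (adjusted p = 0.0279, or 0.33 with an estimated correlation). The unfolded protein response call was lost without control 1, control 4, PSC 13 or PSC 14 (adjusted p from 0.0559 to 0.0919). The unfolded protein response count became 3 without control 1, 8 without control 2 and 2 without PSC 11 or PSC 14. Ddit3 rose by 1.38 (SE 0.23, adjusted p = 0.00227) and Trib3 by 2.17 (SE 0.44, adjusted p = 0.00654). Hsd3b5 lost its call without PSC 11 (adjusted p = 0.0623) or PSC 13 (0.0621) and Slco1a1 without control 1, control 2, PSC 11, PSC 13 or PSC 14 (0.0508 to 0.0769). Hsd3b5 moved to -3.54 without control 3, -5.33 without control 4, -5.13 with edgeR and -5.12 with DESeq2 and Slco1a1 to -5.69 without control 4, -5.32 with edgeR and -5.32 with DESeq2.

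The remaining lists did not pass in PSC (adjusted p from 0.108 to 0.843). They were type I interferon response, xenobiotic cytochrome P450, bile acid synthesis, heme synthesis and degradation and PPAR alpha target and fatty acid oxidation. Others were NRF2 target, hepatocyte secreted protein, pericentral hepatocyte, periportal hepatocyte, circadian clock, immediate early, sinusoidal endothelial cell, erythroid, pancreatic acinar and mesothelial. For heme genes the test pointed down, with a median of 0.06 and a mean of -0.03. The heme oxygenase gene Hmox1 rose by 1.46 (SE 0.29, adjusted p = 0.00559). Fech, for the last enzyme of heme synthesis, fell by 0.82 (SE 0.23, adjusted p = 0.0309). Lymphocyte and Kupffer cell genes fixed in advance that did not pass gave log2 fold changes of -0.63 for Cd3e, 0.51 for Cd8a, -1.01 for Cd4, -1.17 for Cd274, -0.03 for Pdcd1, 1.79 for Foxp3, 0.37 for Igh locus and 0.51 for Clec4f (adjusted p from 0.124 to 0.989). Bile acid genes gave -1.96 for Cyp7a1, -0.41 for Cyp8b1, -0.17 for Abcb11, -0.69 for Slc10a1 and -0.42 for Abcc4 (adjusted p from 0.0659 to 0.727), and other hepatocyte and stress genes 0.09 for Alas1, -0.07 for Nqo1, 0.87 for Cyp2b10, -0.70 for Alb and 2.13 for Cdkn1a (adjusted p from 0.127 to 0.898). Fech lost its call without control 1, control 4, PSC 11, PSC 13 or PSC 14 (adjusted p from 0.0589 to 0.112) or with equal totals (0.0716). Cyp7a1 passed without control 3 (adjusted p = 0.0192) or PSC 11 (0.04), Slc10a1 without PBC 8 (0.0277) and Cdkn1a without control 2 (0.041).

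The last comparison set the autoimmune model against the non-autoimmune one. The T cell, B cell and neutrophil lists were higher in PBC, and the cholangiocyte and matrix lists in PSC, of which those of T cells and cholangiocytes held with an estimated correlation. Cd8a stood at 723 ± 144 in PBC and 48 ± 17.5 in PSC, a log2 difference of 3.93 (SE 0.42, n = 3 and 3). Tspan8, a bile duct gene, stood at 235 ± 92.9 and 1752 ± 383, a log2 difference of -2.96 (SE 0.32). The lists of fatty acid synthesis, xenobiotic P450 and female-biased genes were also higher in PBC, with 4 of 14, 6 of 19 and 5 of 10 genes called, but did not hold with an estimated correlation. Limma called 204 genes higher in PBC and 208 lower among 18390 tested, with 194 and 201 beyond 2-fold. Leaving out 1 library changed the number of higher genes to 103 without PBC 7, 109 without PSC 11, 71 without PSC 13 and 59 without PSC 14. The number of lower genes became 99 without PSC 11, 69 without PSC 13 and 42 without PSC 14.

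The 8 genes highest in PBC over PSC were led by the sulfotransferase gene Sult3a2 with a log2 difference of 5.68 (SE 0.88, adjusted p = 0.00517), and Sult3a1 had 5.11 (SE 0.47, adjusted p = 0.000178). They included the granulocyte genes Ms4a3 with a log2 difference of 5.64 (SE 0.96, adjusted p = 0.00785), Ngp with 4.95 (SE 0.79, adjusted p = 0.00606) and Mpo with 4.69 (SE 0.75, adjusted p = 0.00609). Ctsg had a log2 difference of 5.40 (adjusted p = 0.0171). Prom2, for a membrane glycoprotein, had 2 reads in PSC and a PBC to PSC ratio of 62.6 (95% counting interval 16.8 to 525), with adjusted p = 0.00318. Prss34, a protease gene of basophils and mast cells, had a log2 difference of 4.99 (SE 1.08, adjusted p = 0.0301). Ctsg lost its call without PBC 9 (adjusted p = 0.0696), PSC 13 (0.0586) or PSC 14 (0.0505) and Prss34 without PBC 7, PBC 8, PBC 9, PSC 13 or PSC 14 (0.0543 to 0.134) or with a pseudocount of 0.5 (0.0615). Ms4a3 moved to 4.66 without PSC 13 and 6.49 without PSC 14, Ngp to 5.78 without PBC 7 and 4.20 without PBC 9, Mpo to 4.05 without PBC 9, Sult3a2 to 4.99 without PBC 7, 6.39 without PBC 8, 6.45 without PSC 11 and 4.45 without PSC 14, Sult3a1 to 4.50 without PBC 7, Ctsg to 6.10 without PSC 11 and 4.19 without PSC 13, Prom2 from 5.11 to 5.81 without PSC 14 and 5.89 with DESeq2 and Prss34 to 4.32 without PBC 9 and 5.90 without PSC 11.

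The 8 genes highest in PSC over PBC were led by the epithelial gene Sprr1a with a log2 difference of -7.37 (SE 0.75, adjusted p = 0.000299). They included the receptor subunit gene Gabrp with a log2 difference of -5.40 (SE 0.55, adjusted p = 0.000299) and Mup20 with -5.12 (SE 0.31, adjusted p = 2.97e-06). Duoxa2, Gml and Chil4 had 0 reads in PBC and were higher in PSC by at least 42.6-fold, at least 40.0-fold and at least 57.2-fold (adjusted p = 0.00543, 0.00568 and 0.0336). With 1 library left out, these bounds were 24.8 to 52.9, 23.3 to 49.3 and 8.62 to 98.8, the lowest for Chil4 without PSC 14. Ccl20, a chemokine gene, had 1 read in PBC and a PSC to PBC ratio of 81.9 (95% counting interval 14.4 to 3261), with adjusted p = 0.0124. The adhesion gene Lrtm2 had a log2 difference of -5.59 (SE 1.21, adjusted p = 0.0301). Duoxa2 lost its call without PSC 11 (adjusted p = 0.0523) or PSC 14 (0.0733), Gml without PSC 11 (0.0513) or PSC 14 (0.0759), Chil4 without PBC 7, PBC 8, PBC 9, PSC 11, PSC 13 or PSC 14 (0.0603 to 0.278) or with a pseudocount of 0.5 (0.0556) or edgeR (0.0837), Ccl20 without PSC 11 (0.0601), PSC 13 (0.0703) or PSC 14 (0.102) and Lrtm2 without PBC 7, PBC 9, PSC 11, PSC 13 or PSC 14 (0.0795 to 0.133) or with a pseudocount of 0.5 (0.0528) or DESeq2 (0.085). Sprr1a moved to -8.17 without PBC 9, Ccl20 from -5.34 to -6.04 with edgeR and -6.29 with DESeq2 and Lrtm2 to -4.96 without PBC 7, -6.85 without PBC 8, -4.96 without PBC 9 and -4.74 with edgeR.

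Of 19 T cell genes, 11 were higher (17 over the list alone), and the list was higher in PBC (adjusted p = 0.00016, or 0.0456 with an estimated correlation). The T cell count became 5 without PBC 7, 6 without PBC 9, PSC 11 or PSC 13 and 4 without PSC 14. Leading members were Cd8a with a log2 difference of 3.93 (SE 0.42, adjusted p = 0.000459), Tra/Trd locus with 1.90 (SE 0.26, adjusted p = 0.00236) and Cd8b1 with 3.09 (SE 0.43, adjusted p = 0.00288). Of 13 NK cell and cytotoxicity genes, 3 were higher (6 were higher and 2 were lower over the list alone), and the list was higher in PBC (adjusted p = 0.0186, or 0.294 with an estimated correlation). The NK cell call was lost without PBC 7, PBC 8, PSC 13 or PSC 14 (adjusted p from 0.051 to 0.0742). Nkg7 and Ccl5 led it, Nkg7 with a log2 difference of 1.62 (SE 0.23, adjusted p = 0.00319) and Ccl5 with 1.53 (SE 0.24, adjusted p = 0.00543). Of 10 B cell genes, 5 were higher (9 over the list alone), and the list was higher in PBC (adjusted p = 0.000731, or 0.061 with an estimated correlation). The B cell count became 3 without PBC 7, PBC 9 or PSC 13 and 2 without PSC 11 or PSC 14. Cd79a, of the B cell receptor, gave 2.27 (SE 0.32, adjusted p = 0.00296). Of 5 plasma cell and immunoglobulin genes, 2 were higher (4 over the list alone), and the list was higher in PBC (adjusted p = 0.0242, or 0.204 with an estimated correlation). The plasma cell call was lost without PBC 7 (adjusted p = 0.0846), PSC 11 (0.0736) or PSC 14 (0.0844). The plasma cell count became 1 without PBC 7, PSC 11 or PSC 14. The immunoglobulin loci gave Igl locus with a log2 difference of 2.04 (SE 0.31, adjusted p = 0.00431) and Igh locus with 1.89 (SE 0.38, adjusted p = 0.0191). Of 8 lymphoid aggregate genes, 3 were higher (5 over the list alone), and the list was higher in PBC (adjusted p = 0.00689, or 0.144 with an estimated correlation). The lymphoid aggregate count became 1 without PSC 11 or PSC 14. Cxcl13, a B cell chemokine gene, had a log2 difference of 4.58 (adjusted p = 0.00669), with 2466 normalised reads in PBC 8 against 178 and 234 in the other PBC livers. The checkpoint and regulatory T cell list was higher in PBC (adjusted p = 0.00016, or 0.061 with an estimated correlation). Of its 11 genes limma called 0, with 3 adjusted over the list alone, 5 at an unadjusted p under 0.05, 0 by edgeR and 2 by DESeq2. Igh locus lost its call without PBC 7 (adjusted p = 0.0754), PSC 11 (0.0754) or PSC 14 (0.119). Cxcl13 moved to 3.39 without PBC 8, 5.28 without PBC 9 and 5.60 with edgeR.

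Of 13 neutrophil genes, 6 were higher (11 over the list alone), and the list was higher in PBC (adjusted p = 0.00508, or 0.0766 with an estimated correlation). The neutrophil count became 3 without PBC 9 or PSC 14 and 2 without PSC 13. Of 16 MHC and antigen presentation genes, 2 were higher (9 over the list alone), and the list was higher in PBC (adjusted p = 0.00369, or 0.089 with an estimated correlation). The MHC count became 4 without control 3, 1 without PBC 7, PBC 8, PSC 11 or PSC 13 and 0 without PSC 14. The peptide transporter gene Tap1 gave 1.41 (SE 0.23, adjusted p = 0.00654). Of 14 interferon gamma response genes, 6 were higher (10 over the list alone), and the list was higher in PBC (adjusted p = 0.0183, or 0.158 with an estimated correlation). The interferon gamma call was lost without PBC 7, PSC 11, PSC 13 or PSC 14 (adjusted p from 0.0527 to 0.0576), and with equal totals (0.0818). The interferon gamma count became 3 without PBC 7 and 2 without PBC 8, PSC 11, PSC 13 or PSC 14. The GTPase gene Igtp gave 1.99 (SE 0.28, adjusted p = 0.00275). Of 12 Kupffer cell genes, 2 were higher (7 over the list alone), and the list was higher in PBC (adjusted p = 0.0456, or 0.292 with an estimated correlation). The Kupffer cell call was lost without control 1, control 3, PBC 8, PBC 9, PSC 13 or PSC 14 (adjusted p from 0.0641 to 0.141), and with TMM scaling (0.051), equal totals (0.196) or only the compared groups (0.0725). The Kupffer cell count became 1 without PSC 13 or PSC 14. Marco gave 3.05 (SE 0.50, adjusted p = 0.0068). Of 16 monocyte and recruited macrophage genes, 1 was higher and 5 were lower (2 were higher and 5 were lower over the list alone), and the list was lower in PBC (adjusted p = 0.0304, or 0.292 with an estimated correlation). The macrophage call was lost without control 1, PBC 7, PBC 9, PSC 11 or PSC 14 (adjusted p from 0.0518 to 0.115). Among macrophage genes, 2 were higher and 5 were lower without control 4, 1 was higher and 2 were lower without PBC 7, 0 were higher and 4 were lower without PBC 8 or PBC 9 and 0 were higher and 2 were lower without PSC 11, PSC 13 or PSC 14. The macrophage genes higher in PSC included Mmp12 with a log2 difference of -4.12 (SE 0.42, adjusted p = 0.000299), Trem2 with -2.35 (SE 0.31, adjusted p = 0.00232) and Gpnmb with -3.25 (SE 0.64, adjusted p = 0.0184). The gene higher in PBC was the monocyte marker Ly6c2, with 2.01 (adjusted p = 0.0345). Tap1 lost its call without PSC 14 (adjusted p = 0.0544), Gpnmb without PBC 7, PBC 9, PSC 11, PSC 13 or PSC 14 (0.056 to 0.0874) or with a pseudocount of 0.5 (0.0519) and Ly6c2 without PBC 8, PBC 9, PSC 11, PSC 13 or PSC 14 (0.0943 to 0.143) or with no filter (0.0532) or equal totals (0.0572).

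Of 20 cholangiocyte and ductular reaction genes, 7 were lower (11 over the list alone), and the list was lower in PBC (adjusted p = 0.00021, or 0.0456 with an estimated correlation). Leading members were Spp1 with a log2 difference of -2.72 (SE 0.27, adjusted p = 0.000299), Tspan8 with -2.96 (SE 0.32, adjusted p = 0.000459) and Cldn4 with -3.98 (SE 0.45, adjusted p = 0.000669), and the epithelial adhesion gene Epcam gave -2.17 (adjusted p = 0.00913). Of 24 extracellular matrix and stellate cell genes, 11 were lower (15 over the list alone), and the list was lower in PBC (adjusted p = 0.00112, or 0.061 with an estimated correlation). The matrix count became 7 without PSC 11, 6 without PSC 13 and 5 without PSC 14. Collagen genes lower in PBC included Col3a1 with a log2 difference of -2.58 (SE 0.28, adjusted p = 0.000459), Col1a2 with -1.99 (SE 0.27, adjusted p = 0.00232) and Col1a1 with -2.43 (SE 0.44, adjusted p = 0.0121). Timp1 gave -1.86 (adjusted p = 0.0374). Epcam lost its call without PSC 13 (adjusted p = 0.0569) or PSC 14 (0.0699), Col1a1 without PSC 14 (0.0738) and Timp1 without PBC 7, PBC 8, PBC 9, PSC 11, PSC 13 or PSC 14 (0.0633 to 0.212).

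Of 19 xenobiotic cytochrome P450 genes, 6 were higher (7 over the list alone), and the list was higher in PBC (adjusted p = 0.0136, or 0.132 with an estimated correlation). The P450 call was lost without PSC 11 (adjusted p = 0.0571), and with equal totals (0.0588). The P450 count became 2 without PSC 13 or PSC 14. Cyp2b10 and Cyp2c29 led it, Cyp2b10 with a log2 difference of 3.21 (SE 0.46, adjusted p = 0.00318) and Cyp2c29 with 1.74 (SE 0.24, adjusted p = 0.00268). Of 14 fatty acid synthesis genes, 4 were higher (11 over the list alone), and the list was higher in PBC (adjusted p = 0.00743, or 0.0766 with an estimated correlation). The fatty acid synthesis count became 2 without PBC 7, PSC 13 or PSC 14. Fatty acid synthase and a lipase gene led it, Fasn with a log2 difference of 2.06 (SE 0.29, adjusted p = 0.00282) and Pnpla3 with 3.58 (SE 0.59, adjusted p = 0.00696). Of 10 female-biased liver genes, 5 were higher (9 over the list alone), and the list was higher in PBC (adjusted p = 0.00369, or 0.0706 with an estimated correlation). The female-biased count became 2 without PBC 7, PSC 13 or PSC 14 and 3 without PBC 9 or PSC 11. Besides the sulfotransferases, Cyp3a44 gave 4.61 (SE 0.70, adjusted p = 0.00443). Of 11 bile acid uptake and canalicular export genes, 1 was higher (5 were higher and 1 was lower over the list alone), and the list was higher in PBC (adjusted p = 0.000658, or 0.061 with an estimated correlation). The bile acid transport call was lost with equal totals (adjusted p = 0.073). The sterol exporter gene Abcg8 gave 1.34 (SE 0.22, adjusted p = 0.00669). Of 15 periportal hepatocyte genes, 2 were higher (4 over the list alone), and the list was higher in PBC (adjusted p = 0.0299, or 0.272 with an estimated correlation). The periportal call was lost without PBC 9, PSC 11, PSC 13 or PSC 14 (adjusted p from 0.0604 to 0.1), and with equal totals (0.141) or only the compared groups (0.0707). The periportal count became 1 without control 1, control 2 or PBC 7 and 0 without PBC 9, PSC 11, PSC 13 or PSC 14. Cyp3a44 moved to 3.97 without PBC 7.

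The lists that did not pass between PBC and PSC were inflammatory cytokine and chemokine, acute phase, type I interferon response, dendritic cell, sinusoidal endothelial cell, cell cycle, p53 target and senescence, unfolded protein response and NRF2 target (adjusted p from 0.145 to 0.919). Those of metabolism and other cell types were cholesterol synthesis, bile acid synthesis, basolateral bile acid export and FXR target, heme synthesis and degradation, PPAR alpha target and fatty acid oxidation, hepatocyte secreted protein, pericentral hepatocyte, male-biased liver gene, circadian clock, immediate early and tissue handling, erythroid, pancreatic acinar and mesothelial (adjusted p from 0.0697 to 0.89). The test, the median and the mean differed in sign for dendritic cell (down, 0.16 and -0.35), acute phase (up, 0.04 and -0.08), unfolded protein response (down, 0.00 and -0.11) and male-biased liver gene (down, 0.64 and 0.02). Cd3e, of the T cell receptor complex, differed by 3.02 (SE 0.69, adjusted p = 0.0383). Genes fixed in advance that did not pass gave log2 differences of -0.98 for Krt19, -1.50 for Krt7 and -1.25 for Acta2 (adjusted p from 0.0566 to 0.164) for biliary and stellate cells. Immune and acute phase genes gave 1.95 for Cd4, 2.24 for Cd274, 2.77 for Pdcd1, 0.88 for Foxp3, 0.85 for Cxcl9, 1.79 for Ms4a1, 0.39 for Clec4f, 2.07 for S100a8 and -1.60 for Saa1 (adjusted p from 0.109 to 0.601). Bile acid genes gave 0.76 for Cyp7a1, 0.99 for Cyp8b1, 0.44 for Abcb11, 0.55 for Slc10a1 and 0.41 for Abcc4 (adjusted p from 0.172 to 0.7), and other genes -0.51 for Alas1, 0.16 for Hmox1, 0.16 for Fech, -0.22 for Nqo1, 1.03 for Alb, 0.01 for Mki67 and -0.58 for Cdkn1a (adjusted p from 0.189 to 0.996). Cd3e lost its call without PBC 7, PBC 8, PBC 9, PSC 11 or PSC 14 (adjusted p from 0.0815 to 0.152) or with no filter (0.0592) or equal totals (0.0539). Cd3e moved to 3.63 without PSC 13 and 2.22 without PSC 14. Krt7 passed without control 2 (adjusted p = 0.0255) or control 3 (0.0274) and S100a8 without control 4 (0.0137).

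PBC and PSC shared many of their changes from the controls. Of 18390 genes, 898 were called in the same direction, 726 higher and 172 lower. Independent lists of these sizes would share 115 higher and 27.9 lower. Simulated unchanged groups with the same controls shared at most 1 in 100 runs (mean 0.03) but, with few calls, set no baseline. With controls split 2 and 2 between comparisons, 6 splits shared 125 to 224. Across genes, which are not independent replicates, the covariance of the log2 fold changes was 0.549, against 0.106 simulated and 0.381 to 0.472 with split controls. The correlation was 0.586, against 0.43 simulated and 0.345 to 0.466 with split controls. Shared calls numbered 539 without control 1, 568 without PBC 7, 1875 without PBC 8, 492 without PBC 9, 482 without PSC 11, 589 without PSC 13 and 463 without PSC 14. Lcn2, Timp1, Col1a2, Cd74, Ccl2 and Hmox1 rose in both models.

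Only 3 genes were called in opposite directions, and they are named here after their values were seen. Serpine2, a protease inhibitor gene, had log2 fold changes of -0.97 (adjusted p = 0.0365) in PBC and 1.15 (adjusted p = 0.0134) in PSC. Slc3a1, a cystine transporter subunit gene, had 1.53 (adjusted p = 0.00131) and -1.04 (adjusted p = 0.0107). Gbp4, an interferon-induced GTPase gene, had 1.36 (adjusted p = 0.0263) and -1.16 (adjusted p = 0.0396). Tested directly, PBC differed from PSC by -2.12 (adjusted p = 0.00232) for Serpine2, 2.58 (adjusted p = 0.000245) for Slc3a1 and 2.51 (adjusted p = 0.00358) for Gbp4. In PBC against control, Serpine2 lost its call without control 1, control 2, control 4, PBC 7, PBC 9, PSC 11, PSC 13 or PSC 14 (adjusted p from 0.0529 to 0.134) or with no filter (0.0537) or only the compared groups (0.108) and Gbp4 without control 2 (0.0538) or PBC 7 (0.0588) or with equal totals (0.083) or only the compared groups (0.0703). In PSC against control, Serpine2 lost its call without PSC 13 (adjusted p = 0.0618) or PSC 14 (0.064), Slc3a1 without PSC 13 (0.0595) or PSC 14 (0.0704) and Gbp4 without control 1, control 3, control 4, PSC 11, PSC 13 or PSC 14 (0.0655 to 0.14) or with no filter (0.0541) or equal totals (0.0797).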

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

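Among 121 values screened within the 4 controls, 9 had 1 library far from the other 3 by Dixon's test, and chance alone gives about 1 in 20. The tests of explanation for control 4 were all chosen after the results were seen. The score of immediate early genes was -1.92 in control 4 against 0.48 to 0.78 in the others. Abcc4 stood at 526 in control 4 against 135 to 158 in the others, Kcnk10 stood at 142 in control 4 against 75.7 to 86.8 in the others, and Mki67 stood at 15.3 in control 4 against 33.4 to 35.8 in the others. For genes at 0 in the other controls, the values were 5.18 for Ltf in control 1, 5.55 for Mpo in control 4, 3.89 for Ctsg in control 1, 2.59 for Sprr1a in control 1 and 2.55 for Prss34 in control 3, each a few reads at most.

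Control 4 differed from the other controls in immediate early genes, and 3 explanations were weighed. Another time of day at collection predicted a shift of clock genes in opposite directions. Genes that peak with Dbp differed by 3.02 log2 units on average in control 4, and genes that peak with Arntl by -3.26, so that another time of day may have contributed, although times are not given. Lower depth was excluded, since control 4 had 62.2 M recovered reads, within the range of the other controls. A diseased liver labelled as control was excluded, with Lcn2 at 261 in control 4, no higher than in the other controls.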

How the results depend on the processing

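No called gene among those named changed direction under any alternative, and the counts of called genes were within 1.5 times those reported with either other pseudocount, either other filter, TMM scaling, edgeR and, chosen after seeing the data, models with a symbol only. With equal totals, 853 genes were higher in PBC and 669 lower in PSC, 128 were higher in PBC than PSC, and 578 calls were shared; this scaling moved the median log2 fold change of PBC against control from 0.01 to -0.12. DESeq2 called 913 genes lower in PBC, 1929 lower in PSC, and 590 higher and 623 lower in PBC than PSC. With only the compared groups in the fit, 752 were higher and 89 lower in PBC, and 1853 lower in PSC. Quality weights (4.01 for control 1, 0.289 for PBC 8) gave 2425 higher and 1803 lower in PBC, 3899 and 3404 in PSC, 658 and 701 in PBC against PSC, and 2876 shared calls. For these shifts the cause was not tested. Camera with an estimated correlation called 5 lists and reversed no called list. Splitting the controls, which leaves 2 for each comparison, gave 224, 125, 160, 175, 187 and 169 shared calls. Leaving out 1 library gave 684 to 1818 genes higher and 65 to 1574 lower in PBC, 711 to 1915 higher and 251 to 1899 lower in PSC, 59 to 261 higher and 42 to 301 lower in PBC against PSC, and 463 to 1875 shared calls. The checkpoint and regulatory T cell list, not called in PSC, was called down there with the stricter filter (adjusted p = 0.0262), which leaves fewer of its genes. Of 682 tests of named genes, 637 kept their call with equal totals, 674 with TMM scaling, 658 with edgeR, 618 with DESeq2 and 594 with quality weights. Of 120 list tests, 107 had the same outcome with equal totals and 107 with only the compared groups. Calls lost numbered 12 and 9, and calls gained 1 and 4. Other pseudocounts moved folds of genes near 0, for Ltf in PBC against control to 10.60 and 7.90. Depth limits what low genes can show, with 38.3 to 95.4 M reads per library. No paired analysis was possible because the groups share no replicate numbers.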

Other observations

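Gene groups chosen after the data were seen were tested with fry and adjusted over these groups. Of 19 complement genes, 10 rose in PBC (11 over the group alone), and the group rose (adjusted p = 0.000113, or 0.0494 with an estimated correlation). C4b rose by 2.06 (SE 0.24, adjusted p = 0.000217), C3 by 1.82 (SE 0.29, adjusted p = 0.00181) and C6 by 1.71 (SE 0.21, adjusted p = 0.00035). In PSC 6 rose and 1 fell (9 and 1 over the group alone), and the group rose (adjusted p = 0.000362, or 0.0741 with an estimated correlation). C4b rose by 1.41 (SE 0.24, adjusted p = 0.00215) and Masp1 fell by 1.11 (SE 0.34, adjusted p = 0.0453). Masp1 lost its call without control 1, control 2, control 4, PSC 11, PSC 13 or PSC 14 (adjusted p from 0.0708 to 0.166) or with no filter (0.056) or equal totals (0.0966). Of 18 eosinophil, basophil and mast cell genes, 8 passed the filter, which PBC alone can meet. The group rose in PBC (adjusted p = 0.000927, or 0.107 with an estimated correlation), with 5 called and 2 without PBC 9. It also rose in PSC (adjusted p = 0.026), a call lost without PSC 11 (0.0928) or PSC 14 (0.114). It was higher in PBC than PSC (adjusted p = 0.0406), a call lost without any 1 control, PBC 8, PBC 9, PSC 13 or PSC 14 (0.0546 to 0.122). Both gave 0.359 with an estimated correlation. Ear2, an eosinophil ribonuclease gene, rose in PBC by 1.67 (SE 0.24, adjusted p = 0.000802). Coagulation factor genes rose as a group in PBC (adjusted p = 0.000362, or 0.0741 with an estimated correlation), with 6 of 19 called, 0 to 3 without control 1, control 3, PBC 7, PBC 9 or any 1 PSC liver, and 7 higher and 3 lower without PBC 8. They were higher in PBC than PSC (adjusted p = 0.000642, or 0.0741 with an estimated correlation), with 0 called, and did not pass in PSC against control (adjusted p = 0.482). Iron handling genes and YAP targets did not pass in any comparison (adjusted p from 0.0914 to 0.804), although iron handling passed in PSC without PBC 7 or PBC 9 and in PBC against PSC without PBC 7.

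In PSC all 10 female-biased liver genes tested fell, while of 7 male-biased genes 3 fell (1 without PSC 11 or PSC 13) and Mup20 alone rose, and 3 explanations were tested, of which only that of shared reads was set down before its result was seen. Male PSC livers were excluded by 0 reads on the Y-linked genes in the 3 PSC libraries. A lower share of hepatocyte RNA was excluded by a median log2 fold change of -0.0899 for 19 secreted proteins, against -2.92 for the female-biased genes. Shared reads remain possible for Mup20: the other 10 Mup models (median -2.17) would also fall if their reads went to Mup20. A change in the pattern of growth hormone, which sets sex-biased expression in liver, was not tested.

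The rise of granulocyte genes in PBC had 3 tested explanations, only that of blood formation set down before its result was seen. More residual blood was excluded (highest hemoglobin log2 fold change 0.0306), but not blood richer in granulocytes. Mature neutrophils alone remain possible: precursor genes lay above mature genes by 3.59 log2 units or more in each PBC liver, over the control mean, but had been chosen among the largest increases. For general blood formation the criterion set beforehand was met, with a median of 1.73 for 9 erythroid precursor and megakaryocyte genes, but the 4 that rose, Pf4, Ppbp, Gp9 and Gp1bb, mark platelets and megakaryocytes. An erythroid test added afterwards gave a median of -0.00209 with an upper quartile of 0.78. Formation of granulocytes in the liver or an effect of the adjuvant may explain the rise, and without an adjuvant control neither could be tested.

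Other assignments of the same libraries to groups of the same size were tested, a test chosen after the results were seen. For PBC against control, 1828 genes were called and only 1 of 35 splits, the real one, gave as many, with 117 at most in another. For PSC against control, the figures were 2710 genes, 1 of 35 splits and 516 at most. For PBC against PSC, the 10 splits are too few. Shared calls numbered 898, reached in 1 of 100 splits, and 596 at most in another, which kept the controls together and mixed PBC with PSC livers. List tests called numbered 57, reached in 1 of 100 splits, and 21 at most in another.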
